A study of Mus musculus with 107 samples.

How the data were processed

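Single mouse eggs were profiled by Smart-seq2, which copies whole polyadenylated transcripts of 1 cell and does not mark the strand of origin. Per the labels' protocols, germinal vesicle oocytes of C57BL/6J females, given 5 IU PMSG 48 h earlier, were held in 2.5 µM milrinone and matured in culture. Eggs carried a homozygous mutation of Mos or were wildtype. A further set of wildtype eggs was exposed to 10 mM strontium chloride for 2 h in medium without calcium, beginning 15 to 16 h after germinal vesicle breakdown, and all eggs were collected at 38 to 40 h. Strontium triggers calcium release and starts development without sperm. The mutant eggs bore the names M1, M2 or M3, which the labels do not define. The deposited egg table gave each egg a number of growths, also undefined, which equalled the number in the mutant group's name and was 1 for each wildtype egg.

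The deposited values were counts per gene, whole numbers that were not normalised, for 21564 gene symbols in 107 eggs. Per the submitters' processing notes, reads were aligned with STAR and counted with HTSeq, with GRCm38 and mm10 named as the build. Versions, annotation and strand setting are not given in the sources used here. Of the symbols, 88.9% were found in the names of the reference annotation used here (GENCODE M21, GRCm38), which served only for positions, lengths and 3' UTRs. Reads shared by near-identical copies, such as the Usp17l, Zscan4, Dux, Fbxw and ribosomal protein families, calmodulin and histone H3.3 genes, could have been split or lost by the counting, so the values of these genes are uncertain, as are those of overlapping and antisense genes.

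Each sample was 1 egg and no label ties eggs to animals or cultures, so eggs were not used as replicates. Counts were summed per group and batch into 9 sums, and the batch term takes out shifts shared by all groups of a batch. The p-values measure only how far groups shifted differently between batches, which may be technical, on 3 residual degrees of freedom. M1, M2 and M3 shared plates and may share animals, so their sums may not be independent. Each batch had 1 wildtype sum. Activated eggs formed 1 sum, in batch 2, assumed to vary like the other groups, and their plate and treatment cannot be told apart. Their fitted fold rests on wildtype eggs of both batches after the batch term, so it can differ from the ratio within batch 2. edgeR 4.0.16 (R 4.3.3) fitted group and batch with TMM scaling, its expression filter with a minimum count of 10, and robust quasi-likelihood F tests, with Benjamini-Hochberg adjustment over 13832 genes and a threshold of 0.05. The mutant fold was the mean of the 3 mutant groups over wildtype. Mutant groups were compared in 9 sums per group and plate, with the plate as a block, over 11609 genes, and plates of batch 2 may share animals. Plates were taken from the library names. The deposited egg table instead divides batch 1 into a plate A, with 5 wildtype and 2 mutant eggs, and a plate B, with 7 mutant eggs, so that only the former held both genotypes, and the design fixed beforehand had taken batch 1 as 1 plate. Standard errors of log2 folds were the fold divided by the square root of F.

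Before the data were examined, 26 gene lists, the tests, the alternatives and the rule for named genes were fixed. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The rule took the 8 highest and 8 lowest folds among called genes of at least 4 log2 CPM, 2-fold change and the same sign in both batches, without predicted genes, clones and pseudogenes (5 and 5, over plates, for mutant groups), plus up to 3 called members of each list by p, or else its most abundant member, and Mos. Of the genes this rule took, 4 are not reported here and were not replaced. Symbols in the lists were matched through older names after the data were seen, and 665 of 691 entries were found. CPM values given for single genes are TMM-scaled unless called raw. Since polyadenylated transcripts are copied and values are relative to totals, a rise or fall need not be a change in amount per egg.

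Alternatives were RLE and upper quartile scaling, no filter, DESeq2 1.42.0, limma 3.58.1 voom, eggs thinned to 68353 counts and mean log2 CPM over eggs. Further ones were a fold of at least 2, no mitochondrial genes, no batch or plate term, sums per plate, and mutant eggs of a batch in 1 sum. Each sum was also left out in turn. The means added 0.5 to each count before scaling by the egg's total, so a count of 0 scored higher in shallower eggs. Other alternatives were added after the data were seen. These left out eggs under 10000 counts, egg 8 of M3, eggs 6 and 21 of M1, or 9 wildtype eggs with over 35% of counts in 50 genes, used the plates of the deposited table, and reran the test of batch difference and the correlation of responses. Simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, all of at least 4 log2 CPM, were tested in the same fits. Recovery of genes below that level was not measured. For mutant against wildtype 60% and 98% were recovered, for activated against wildtype 15% and 78%, for mutant against activated 18% and 87%, for M2 against M1 34% and 94%, for M3 against M1 41% and 95%, and for M3 against M2 34% and 99%. Poisson intervals of 95% and floors of 3 counts over a sum cover counting error only, because amplified reads are not independent molecules.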

Results

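Counts were obtained from 107 single eggs: 29 wildtype (5 in batch 1, 24 in batch 2), 61 mos mutant (22 M1, 18 M2 and 21 M3, of which 9 in batch 1) and 17 strontium-activated wildtype eggs, all in batch 2. Totals ran from 44 to 9132471 counts per egg. Medians in batch 1 were 8144112 for wildtype and 7031161 for mutant eggs. In batch 2 they were 207420 for wildtype, 605366 for mutant and 796582 for activated eggs. Summed counts ranged from 5436993 (wildtype, batch 2) to 36209306 (wildtype, batch 1). There were 3 mutant eggs that held only 44, 582 and 1526 counts. At an equal depth of 60000 counts, a mean of 5202 ± 604 genes was detected in wildtype eggs of batch 2 (SD over 24 eggs), 6361 ± 867 in mutant eggs (49 eggs) and 6724 ± 257 in activated eggs (17 eggs). In batch 1 the means were 6235 ± 248 (5 eggs) and 6610 ± 372 (9 eggs).

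Mos encodes the kinase that drives MAP kinase signalling in metaphase II eggs and lies on chromosome 4 at 3870657 to 3872105 of GRCm38. It is on the minus strand, in 1 exon with the coding sequence at 3870786 to 3871814. Raw Mos levels in wildtype sums were 6.52 CPM (Poisson 95% interval 5.71 to 7.40) in batch 1 and 31.6 (27.1 to 36.7) in batch 2. The mutant sums held 5.72 and 13.3 CPM for M1, 0.868 and 8.15 for M2, and 1.45 and 3.67 for M3, in the order of batches. Activated eggs held 5.33 (4.17 to 6.71). Mos was lower in mutants by a log2 fold of -2.10 ± 0.40 (edgeR adjusted p = 0.0029, 6 mutant and 2 wildtype sums) and in activated eggs by -2.71 ± 0.75 (edgeR adjusted p = 0.0224). At least 1 read was seen in 15 of 29 wildtype, 45 of 61 mutant and 10 of 17 activated eggs. Once eggs were thinned to 60000 counts these numbers were 9 of 29, 16 of 58 and 3 of 17. In wildtype sums 1 egg held 37.3% of Mos counts in batch 1 and 36% in batch 2, where 10 of 24 eggs held any. Median raw Mos levels per egg were 6.13 CPM in wildtype and 1.47 in mutant eggs of batch 1. In batch 2 they were 0 and 3.12, with fewer total counts per wildtype egg. The fall in batch 2 was thus seen in sums and not in medians. The library labelled M1 egg 6 of batch 1 held 110 of the 150 Mos counts of its sum (17.9 raw CPM), above the highest wildtype egg of that batch (11.2). The library labelled M1 egg 21 of batch 2 held 92 of 137. Without these eggs, chosen for their Mos counts, the M1 sums held 1.99 (1.42 to 2.72) and 4.67 raw CPM (3.41 to 6.25), and the mutant fold was -2.59 ± 0.42 (edgeR adjusted p = 0.00118). Wildtype sums were kept whole in that fit. Single eggs held most of the few counts in batch 1 of M2 (12 of 14, egg 2) and M3 (20 of 30, egg 1) as well, and the rest of these sums held 0.251 and 0.683 raw CPM. The nature of the mutation is not given in the sources used here, so transcripts of the mutant allele may be counted and Mos reads do not check the labels of these libraries.

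The comparison of mutant with wildtype eggs asks how the egg transcriptome differed with the mutation of Mos. Mapk3, the kinase ERK1 that acts below Mos (chromosome 7, 126759601 to 126765819), rose by a log2 fold of 2.25 ± 0.22 (edgeR adjusted p = 1.4e-05). Its level was 81.6 and 70.8 CPM in wildtype sums, and 490, 455 and 445 in M1, M2 and M3 of batch 1 and 249, 288 and 310 in batch 2. Fxr2, a relative of the fragile X protein, rose by 3.88 ± 0.45, Calm2, a calmodulin gene, by 3.72 ± 0.39, and Dnmt3l, a cofactor of DNA methylation, by 2.92 ± 0.22. Zfp296, a zinc finger gene (chromosome 7, 19577287 to 19580656), fell by 2.57 ± 0.23 on the log2 scale, Elovl5, a fatty acid elongase, by 2.09 ± 0.20, and the laminin gene Lama5 by 1.98 ± 0.17. Gdf9, a growth factor secreted by the oocyte, fell by 1.19 ± 0.15, Zar1, which masks stored mRNA, by 1.27 ± 0.16, and the oocyte linker histone H1f8 by 1.24 ± 0.17.

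Of 13832 genes tested, 1298 differed (741 higher and 557 lower, edgeR adjusted p under 0.05). All 1298 had the same sign in both batches, against 65.4% of all tested genes. The fit that called them used both batches, so genes whose folds disagreed could hardly pass, and this agreement is not a replication. Over all tested genes the mutant folds of the 2 batches correlated at 0.296. The other genes of largest rise were Rhoh (3.09 ± 0.44), M6pr, the smaller mannose 6-phosphate receptor (3.01 ± 0.36), Zfp61 (2.87 ± 0.39) and Lsm10 (2.82 ± 0.39). The other genes of largest fall were Klhl21 (-2.08 ± 0.47), the cleavage and polyadenylation factor Cpsf1 (-1.80 ± 0.21), Arrdc2 (-1.73 ± 0.21) and Alg2 (-1.69 ± 0.27). In 9 of the 24 wildtype eggs of batch 2 the 50 most abundant genes held 35.8 to 45.9% of counts, against 16.4 to 30.1% in the 95 other eggs of at least 10000 counts. Without these 9 eggs 1094 genes were called, all 1298 kept their direction, and Cdk1, Cdc6, Ube2c, Spry1, Cirbp and Nop58 no longer passed. With means of log2 CPM over eggs 1199 of the 1298 kept their direction, and 1236 when near-empty eggs were left out. The balance of calls evened out or turned with RLE scaling (687 higher and 696 lower), with eggs thinned to equal depth (595 and 611) and without the batch 2 sum of M1 (554 and 636). It leaned further to higher calls with a fold of at least 2 (589 and 225) and with mutant eggs of a batch in 1 sum (758 and 395). The count was 409 with sums per plate and 51 without a batch term. Without the batch 2 sum of wildtype it was 755 (512 higher and 243 lower), and without the batch 1 sum of M1 782.

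**Figure D1:**
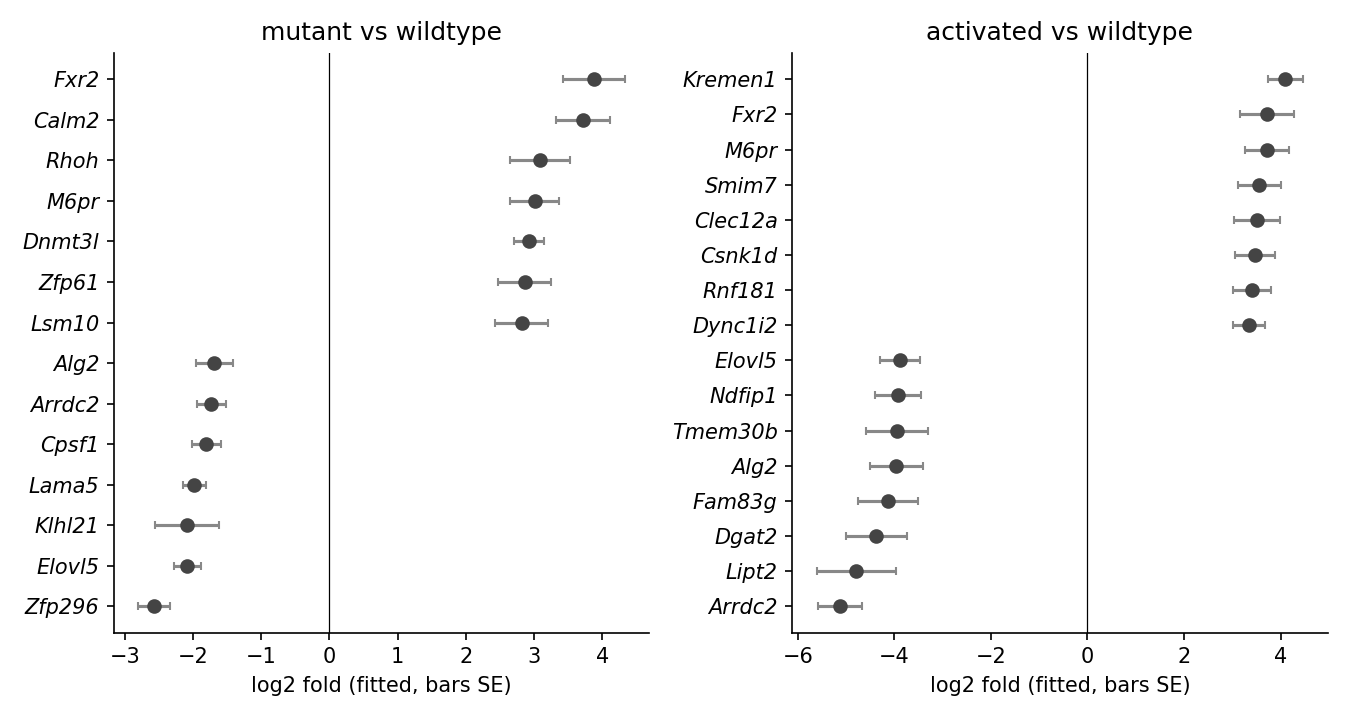
Log2 fold with standard error for the named genes of largest rise and fall in mutant against wildtype (left, 7 and 7) and activated against wildtype (right, 8 and 8) sums. Fxr2, M6pr, Elovl5, Arrdc2 and Alg2 stand in both panels, with Arrdc2 at -1.73 and -5.13.

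Among cell cycle lists, the MOS and MAP kinase cascade had 2 of 15 tested members that rose (Mapk3 and the checkpoint kinase Bub1, 1.02 ± 0.23) and 1 that fell (Mos), with the same counts adjusted over the list alone. Of 21 transcripts known to respond to ERK, 2 rose, Spry1 (1.23 ± 0.34) and Spry4 (0.81 ± 0.17), both inhibitors of the pathway, and 19 did not pass (2 higher adjusted over the list alone). In the list of M-phase promoting and cytostatic factors 3 of 20 rose and 1 fell, also adjusted over the list alone. The risers were Ensa, an inhibitor of the phosphatase PP2A, at 2.23 ± 0.29, Cdk1 at 1.91 ± 0.53 and Cdc25c at 2.99 ± 0.67. The anaphase promoting complex list had 1 riser, Ube2c (1.98 ± 0.53), and 2 that fell, Anapc2 (-1.18 ± 0.19) and separase, Espl1 (-0.98 ± 0.17), of 20 (1 and 3 adjusted over the list alone). Of 22 checkpoint and kinetochore members 3 rose, among them Bub3 (1.30 ± 0.20) and Ttk (0.68 ± 0.19), and none fell (4 and 0 adjusted over the list alone). Of 26 spindle and microtubule members 4 fell, with Kif23 at -0.78 ± 0.17, Tuba1c at -1.20 ± 0.29 and Tubb6 at -0.83 ± 0.20 (Tubb6 was 0.90 as a mean log2 CPM over eggs). Adjusted over the list alone, 2 rose and 4 fell. Cohesin and condensin had 1 of 21 lower (Ncapd3, -0.64 ± 0.18; 0 adjusted over the list alone). Replication had 2 of 27 higher (Gins2, 1.10 ± 0.25, and Cdc6, 0.91 ± 0.25; 2 adjusted over the list alone). None of 24 cortical actin and 23 DNA damage members passed, adjusted over the list alone or not.

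Among lists of egg function, 3 of 28 mRNA decay members rose and 3 fell (4 and 4 adjusted over the list alone), with Cnot1 at 0.92 ± 0.20, Edc4 at -1.05 ± 0.18 and Cnot3 at -0.68 ± 0.17. Of 26 translational control members 4 rose and 2 fell (5 and 3 adjusted over the list alone), with Zar1l at 1.94 ± 0.50 and Cirbp at 1.06 ± 0.27. Of 28 maternal effect genes 4 rose and 6 fell (6 and 7 adjusted over the list alone), with Oas1c at 0.96 ± 0.21, Nlrp9b at 0.81 ± 0.18 and Padi6 at -0.95 ± 0.19. The list of zona pellucida and secreted genes had 4 higher and 4 lower of 23 (5 and 6 adjusted over the list alone), with Cd9, needed for sperm fusion, at 1.85 ± 0.34. Chromatin and methylation factors had 4 higher and 3 lower of 29 (5 and 6 adjusted over the list alone), with H3f3a at 2.17 ± 0.29 and Uhrf1 at -1.14 ± 0.17. Calcium handling had 4 higher and 1 lower of 21 (5 and 1 adjusted over the list alone), with Cacna1h at -1.15 ± 0.18. Of 27 zygotic activation transcripts 2 rose (4 adjusted over the list alone), Arg2 (1.27 ± 0.28) and Duxf3. For Duxf3, 171 mutant counts against 1 wildtype count gave a ratio of 63.6 (interval 11.3 to 2530). Egg 8 of M3 gave most of these Duxf3 counts (210 raw CPM in that egg). As a mean log2 CPM over eggs, where 0 counts score higher in shallower eggs, the Duxf3 difference was -0.25.

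Most housekeeping lists held called genes in both directions. Proteasome genes had 6 higher and 3 lower of 34 (8 and 4 adjusted over the list alone), such as Psmd12 (1.34 ± 0.24), Psma7 (-1.42 ± 0.18) and Psmb3 (-1.10 ± 0.24). The nuclear respiratory chain had 5 and 5 of 48 (6 and 7 adjusted over the list alone), such as Sdhd (2.37 ± 0.43), Cox5b (-1.54 ± 0.25) and Atp5f1a (-1.10 ± 0.20). Ribosomal proteins had 1 higher and 3 lower of 54 (0 and 2 adjusted over the list alone), with Rplp0 at -1.26 ± 0.21 and Rplp2 at -1.04 ± 0.28. Nucleolar genes had 1 higher, Utp4 (1.35 ± 0.24), and 2 lower of 29, Nop56 (-0.70 ± 0.18) and Nop58 (-0.81 ± 0.24), with 2 and 2 adjusted over the list alone. The stress list had 1 lower of 26, Prdx2 (-0.87 ± 0.18; 1 adjusted over the list alone). None of 9 mitochondrially encoded genes passed (mt-Co1, -0.40 ± 0.26), adjusted over the list alone or not. The same held for 16 granulosa and cumulus (Serpine2, -0.44 ± 0.19), 3 blood (Laptm5, -0.15 ± 0.39) and 7 theca, stroma and endothelium markers (Pecam1, -0.26 ± 0.23). Camera called 0 of the 26 lists, with 0 at an unadjusted p under 0.05, 0 with an estimated correlation and 0 by fry. In 16 lists the median fold, the mean fold and camera's direction did not share 1 sign. By fry's test for change in either direction, 21 of the 26 lists had an adjusted p under 0.05. That test asks whether members changed at all, not whether they changed more than other genes. Lists with 0 called members passed too, such as cortical actin (fry adjusted p = 0.00371) and DNA damage (fry adjusted p = 0.00121). It therefore does not single out lists.

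The comparison of activated with unactivated wildtype eggs gives the transcript differences seen after strontium, which cannot be told apart from those of plate. Of 27 tested members of the list of zygotic genome activation 14 rose, 0 fell and 13 did not pass (22 higher and 0 lower adjusted over the list alone; camera adjusted p = 7.07e-11, and adjusted p = 0.452 with an estimated correlation). In batch 2, Zfp352 (chromosome 4, 90218820 to 90225702) had 1448 counts in activated and 0 in wildtype eggs, at least 154-fold higher. Usp17la was at least 96.7-fold higher (909 counts against 0), and Duxf3 had a ratio of 177 (interval 31.6 to 7000). Zona pellucida and secreted genes fell in 9 of 23 and rose in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 7.75e-04). With an estimated correlation this adjusted p was 0.745. Examples were H1f8 at -3.39 ± 0.33, Gdf9 at -2.54 ± 0.29 and Zp3, a sperm-binding coat protein, at -2.99 ± 0.40 (Zp3 was 0.082 as a mean log2 CPM over eggs).

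In all, 1797 of 13832 genes differed (783 higher, 1014 lower; edgeR adjusted p under 0.05). Activated eggs were 1 sum in 1 batch, so this difference has no replicate of its own. Under upper quartile scaling 54.1% of calls were higher, in place of 43.6%, and the median log2 fold of all genes moved from 0.15 to 0.30. Voom gave 51.3% higher, and means over eggs without near-empty eggs 58.6% (3429 higher and 2423 lower). With sums per plate 666 genes were called, without a batch term 196, and without the 9 wildtype eggs whose counts lay in few genes 1533 (644 higher and 889 lower). Kremen1, a receptor for the Dickkopf inhibitors of Wnt signalling, rose by 4.10 ± 0.37, M6pr by 3.71 ± 0.45, Smim7 by 3.56 ± 0.45 and Clec12a by 3.51 ± 0.48. Further rises were those of the casein kinase Csnk1d by 3.47 ± 0.42, the ubiquitin ligase Rnf181 by 3.40 ± 0.40 and the dynein chain Dync1i2 by 3.35 ± 0.33. Fxr2 had a ratio of 28.7 in batch 2 (interval 9.72 to 140; chromosome 11, 69632990 to 69653297). The falls were led by Arrdc2 (-5.13 ± 0.45), Lipt2 (-4.79 ± 0.82), Dgat2, which makes triglycerides (-4.38 ± 0.63), Fam83g (-4.13 ± 0.61), Alg2 (-3.96 ± 0.55), Tmem30b (-3.94 ± 0.65), Ndfip1 (-3.93 ± 0.48) and Elovl5 (-3.88 ± 0.41).

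Camera called no cell cycle list between activated and wildtype eggs, the lowest adjusted p being 0.0919 for cohesin and condensin, and most members of each list did not pass. Without egg 8 of M3 in the fit cohesin and condensin were called as lower (camera adjusted p = 0.0252, and adjusted p = 0.753 with an estimated correlation). Checkpoint and kinetochore genes had 2 higher and 4 lower of 22 (2 and 5 adjusted over the list alone), with Bub1b at -3.77 ± 0.45, Ndc80 at -3.18 ± 0.47 and Bub1 at 1.41 ± 0.33. Cohesin and condensin had 4 lower of 21 (6 adjusted over the list alone), with Smc3 at -3.41 ± 0.47, Smc4 at -3.29 ± 0.38 and Ncapg at -2.61 ± 0.34. In the MOS and MAP kinase list 3 of 15 rose and 2 fell, also adjusted over the list alone, with Mapk3 at 2.24 ± 0.29 and Map2k2 at -2.41 ± 0.44. Dusp6, a phosphatase induced by ERK (chromosome 10, 99263231 to 99267489), rose by 3.59 ± 0.86 and Spry4 by 1.54 ± 0.25, while Dusp1 fell by 1.27 ± 0.29. Their list had 2 higher and 1 lower of 21, also adjusted over the list alone. M-phase and cytostatic factors had 4 higher and 3 lower of 20 (4 and 5 adjusted over the list alone), with Ensa at 2.43 ± 0.39 and Fbxo5, the APC inhibitor Emi1, at -1.91 ± 0.34. Cdc25c had a ratio of 70.5 in batch 2 (interval 12.5 to 2800). The anaphase promoting complex list had 0 higher and 3 lower of 20 (1 and 4 adjusted over the list alone), among them Espl1 (-1.82 ± 0.30). Replication had 1 higher and 3 lower of 27 (1 and 5 adjusted over the list alone), among them Orc4 (-1.81 ± 0.36) and Mcm4 (-1.73 ± 0.40).

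Stored-mRNA regulators included Zar1 (-3.60 ± 0.31) and Lsm14b (-2.74 ± 0.39) among 2 higher and 3 lower of 26 (4 and 3 adjusted over the list alone). Edc4 (-1.98 ± 0.32) and Dcp1a (-1.61 ± 0.28) were among 3 higher and 5 lower of 28 decay factors (3 and 6 adjusted over the list alone). Chromatin factors had 3 higher and 7 lower of 29 (3 and 8 adjusted over the list alone), with Dnmt3l at 2.36 ± 0.28, Tet3 at -1.75 ± 0.31 and Uhrf1 at -1.76 ± 0.30. Maternal effect genes had 1 higher and 4 lower of 28, also adjusted over the list alone, with Padi6 at -2.42 ± 0.35. Nucleolar genes had 2 higher and 6 lower of 29 (4 and 6 adjusted over the list alone), with Dkc1 at -1.83 ± 0.38. Actin genes had 1 higher and 5 lower of 24 (3 and 6 adjusted over the list alone), with Spire1 at -1.53 ± 0.32 and Pfn1 at -1.07 ± 0.30 (Pfn1 was 0.23 as a mean log2 CPM over eggs). In the stress list 2 rose and 2 fell of 26, also adjusted over the list alone, with Hsp90aa1 at -1.73 ± 0.38 and Hsph1 at -1.43 ± 0.35 (0.42 as a mean log2 CPM over eggs). Hmox1, the heme oxygenase, was at least 21-fold higher in batch 2 (197 counts against 0). The p53 target Cdkn1a rose by 3.57 ± 0.79 and Brca1 fell by 1.30 ± 0.33 in a DNA damage list with 1 and 1 of 23, also adjusted over the list alone. The granulosa and cumulus marker Serpine2 was the 1 of 16 that fell (-2.01 ± 0.32; 1 adjusted over the list alone). The list's median over eggs was 112 CPM in activated and 205 in wildtype eggs of batch 2.

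**Figure D2:**
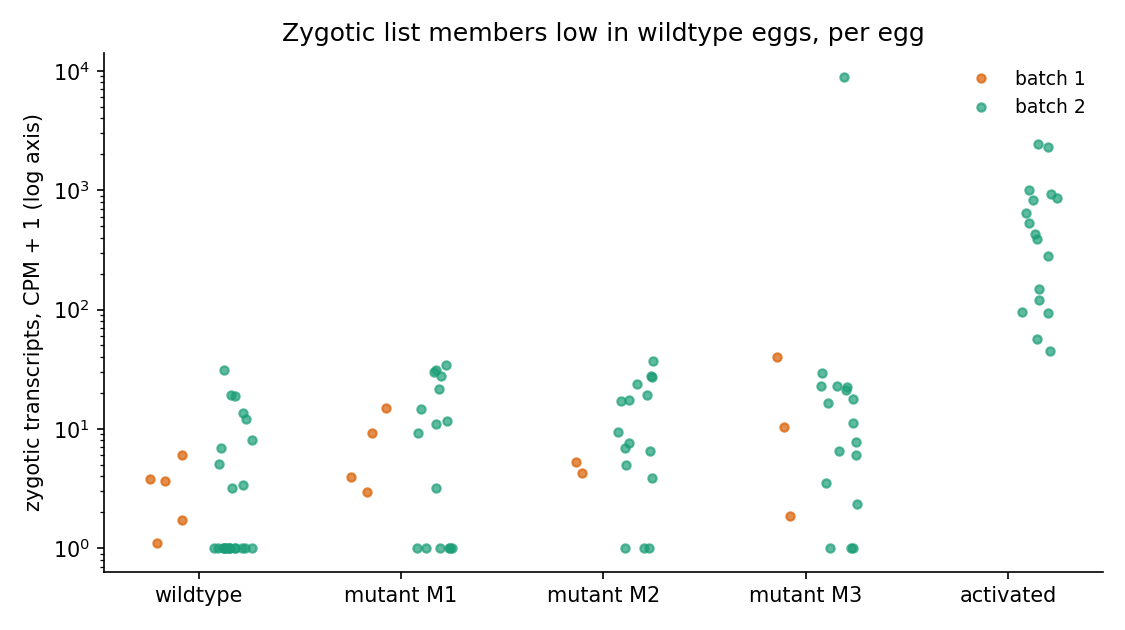
Summed CPM (log axis, 1 added) of zygotic list members under 1 CPM in the batch 1 wildtype sum, per egg, for each group and batch, with eggs under 10000 counts left out. Activated eggs lie between 43.6 and 2410, wildtype eggs reach 29.9, and mutant eggs reach 39 apart from egg 8 of M3 at 8930.

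Mutant and activated eggs were then compared directly. Zar1 was higher in mutants by 2.32 ± 0.27, H1f8 by 2.14 ± 0.29, Zp3 by 2.86 ± 0.38, Bub1b by 3.15 ± 0.41 and Smc4 by 2.73 ± 0.35. Arrdc2 was higher by 3.40 ± 0.40 and Txnip, an inhibitor of thioredoxin, by 2.96 ± 0.32 (edgeR adjusted p = 3.95e-05 for Txnip). Dusp6 was lower in mutants by -4.02 ± 0.71, Cdkn1a by -2.52 ± 0.61, Ercc4 by -2.46 ± 0.41, Rplp0 by -1.91 ± 0.28, Tram1 by -1.76 ± 0.23 and Mkrn1 by -1.75 ± 0.29. Zfp352 had 0 counts in M1 and M2 of both batches, 12 in M3 of batch 1 and 171 in M3 of batch 2, of which 170 came from egg 8. Mos did not pass the test (0.60 ± 0.63, edgeR adjusted p = 0.7). In all 670 of 13832 genes differed (474 higher, 196 lower; edgeR adjusted p under 0.05). Under upper quartile scaling the share higher was 51.5% in place of 70.7%. The balance turned without a batch term (3 higher and 32 lower) and with means over eggs without near-empty eggs (1462 higher and 2203 lower), while all 670 genes kept their direction under both. Without the 9 wildtype eggs whose counts lay in few genes 521 were called (368 higher and 153 lower).

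Camera called 6 lists between mutant and activated eggs. The zygotic list was lower in mutants in 14 of 27 (21 adjusted over the list alone; camera adjusted p = 6.99e-16, and adjusted p = 0.484 with an estimated correlation). The zona and secreted list was higher in 6 of 23 (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.26e-04, and adjusted p = 0.492 with an estimated correlation), with Astl, the protease ovastacin, at 2.07 ± 0.36. Checkpoint genes were higher in 3 of 22 (4 adjusted over the list alone; Ndc80, 2.51 ± 0.43) and ERK-responsive genes lower in 1 of 21 (1 higher and 3 lower adjusted over the list alone). Both stood at a camera adjusted p of 0.0201 and an adjusted p of 0.492 with an estimated correlation. Of 34 proteasome genes 1 was higher, Psma7 (1.75 ± 0.31; 1 adjusted over the list alone), and of 48 respiratory chain genes 0 passed, adjusted over the list alone or not. Both stood at a camera adjusted p of 0.049. With an estimated correlation these had adjusted p = 0.589 and 0.492. Cohesin and condensin had 4 higher of 21, also adjusted over the list alone (Ncapg, 2.50 ± 0.32; Smc3, 2.67 ± 0.43), without a camera call. Without egg 8 of M3 they were called (camera adjusted p = 0.0464, and adjusted p = 0.424 with an estimated correlation). Without eggs 6 and 21 of M1 the chromatin list was called as higher (camera adjusted p = 0.0455, and adjusted p = 0.455 with an estimated correlation). Serpine2 was higher in mutants by 1.57 ± 0.30.

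The folds of mutant and of activated over wildtype eggs were compared across genes. Over 13832 genes, the log2 fold of mutants in batch 1 and that of activated eggs in batch 2, which share no egg, had a Pearson correlation of 0.277 and a Spearman correlation of 0.323. Over 6094 genes of at least 4 log2 CPM Pearson's value was 0.519. Genes are not independent replicates and no p is given. With shared wildtype eggs the correlation was 0.648, against 0.481 in 20 simulations of unchanged groups. The covariance was 1.68 against 0.577, a difference of 1.11. Measured without a shared egg it was lower, at 0.423 with mutants of batch 1. Within batch 2, with wildtype eggs split at random, it was 0.635. The difference of 1.11 can therefore not be taken as the part beyond shared controls. Of the called genes, 428 were higher and 356 lower in both comparisons, such as Mapk3, Calm2 and Dnmt3l, and Zar1, Gdf9 and Elovl5. Independent lists would share 41.9 and 40.8, and simulated unchanged groups shared a mean of 0.1 and 0.15. Few genes can be called where no group differs, so the simulated overlaps were bound to be small. Part of the excess over independent lists may come from the shared controls. Within batch 2 and with wildtype eggs split at random over 20 draws, the correlation was 0.297. The mutant folds of batch 1 and batch 2 correlated at 0.296, and at 0.574 from 4 log2 CPM.

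**Figure D3:**
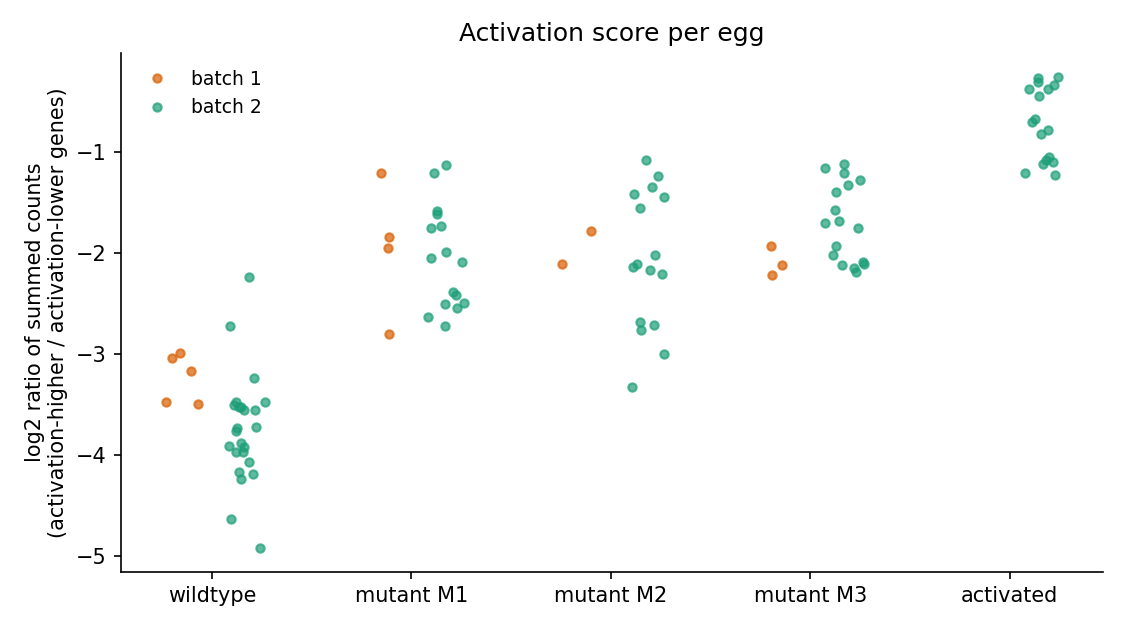
Log2 ratio, per egg, of summed counts of 781 genes higher and 1213 genes lower in activated than wildtype eggs of batch 2, for each group and batch. In batch 1, whose eggs took no part in choosing the genes, wildtype eggs lie between -3.49 and -2.99 and mutant eggs between -2.80 and -1.21.

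The mutant groups M1, M2 and M3 were compared on 3 plates. Zp2 (chromosome 7, 120126772 to 120145291) and Zp1, both zona pellucida proteins, were lower in M3 than in M1 by -1.79 ± 0.23 and -1.35 ± 0.20 (edgeR adjusted p = 0.0396 for both). Padi6, a subcortical complex member, was lower by -1.53 ± 0.23, and the F-box genes Fbxw18 and Fbxw16 by -2.01 ± 0.29 and -1.50 ± 0.23. Usp17la was the 6th call and the only one higher in M3, and 745 of its 746 counts in M3 of batch 2 came from egg 8. No gene differed between M2 and M1 (0 of 11609 by edgeR; 718 at an unadjusted p under 0.05, 28 by DESeq2, 4 by voom). Between M3 and M2 the numbers were 0 by edgeR, 334 at an unadjusted p under 0.05, 2 by DESeq2 and 3 by voom. Mos was -0.98 ± 0.64 in M2 and -1.62 ± 0.63 in M3 relative to M1, and -0.65 ± 0.64 in M3 relative to M2, without a call. Without M1 eggs 6 and 21, which held most Mos counts of M1, the values relative to M1 were 0.17 ± 0.68 in M2 and -0.46 ± 0.66 in M3. The 6 genes were 0 without these 2 eggs (644 at an unadjusted p under 0.05), where Zp2 and Zp1 both had an edgeR adjusted p of 0.855. They were 0 with the plates of the deposited table, 0 without the plate block, and from 0 to 11 with a sum left out. Where the names M1 to M3 were set from the RNA itself, these differences are not independent evidence.

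Camera also called lists between the mutant groups. Zona pellucida and secreted genes were lower in M3 than M1, with 2 of 22 called (8 adjusted over the list alone; camera adjusted p = 2.71e-13, and adjusted p = 0.246 with an estimated correlation). The respiratory chain (0 of 48, 2 lower adjusted over the list alone, camera adjusted p = 4.68e-15) and proteasome (0 of 34, 2 lower adjusted over the list alone, 6.49e-08) were lower too, each with adjusted p = 0.246 with an estimated correlation. Maternal effect genes (1 of 28 lower, 2 adjusted over the list alone, camera adjusted p = 1.71e-05) and ribosomal proteins (0 of 50, also adjusted over the list alone, 4.49e-05) had adjusted p = 0.468 and 0.462 with an estimated correlation. The zygotic list was higher in M3 than M1 (camera adjusted p = 0.00195, and adjusted p = 0.318 with an estimated correlation) and than M2 (3.26e-06, and adjusted p = 0.378 with an estimated correlation). Without egg 8 of M3 these camera adjusted p were 0.818 and 0.891. M2 was lower than M1 in 8 lists by camera, led by zona and secreted genes (2.85e-09) and maternal effect genes (4.14e-09), both with adjusted p = 0.351 with an estimated correlation. The granulosa and cumulus markers moved with them, with a median log2 fold of -1.76 (0 of 10 called, 2 lower adjusted over the list alone; camera adjusted p = 3.86e-04, and adjusted p = 0.351 with an estimated correlation). These markers stood at 1170 CPM in M1 egg 11, against a median of 252 in M1 eggs of batch 2. M1 eggs 6 and 21 held 611 and 638 CPM. Few genes for their depth were detected in M1 eggs 11 and 21 (5779 and 4547), and in M2 egg 14 (2807, at 185 CPM). Without eggs 6 and 21 the list was still lower (camera adjusted p = 6.68e-04, and adjusted p = 0.402 with an estimated correlation). Egg 11 alone was not left out, so its part in the fall was not tested. M3 differed from M2 in 6 lists, led by mitochondrially encoded genes, which were higher (1.21e-07, and adjusted p = 0.422 with an estimated correlation). Egg 8 of M3 held 2.69% mitochondrial counts. Without it the camera adjusted p of this list was 3.04e-04, and 0.671 with an estimated correlation. The granulosa and cumulus markers were higher as well (median log2 fold 0.42; 0 of 10 called, 2 higher adjusted over the list alone; camera adjusted p = 0.013, and adjusted p = 0.422 with an estimated correlation). With an estimated correlation the lowest adjusted p over all lists was 0.351 for M2 against M1 and 0.378 for M3 against M2, and fry called 0 lists in each of the 3 comparisons.

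Whether the mutant effect differed between batches was tested as an interaction. Each batch held 1 wildtype sum, so the spread came only from the 3 mutant groups. A deviation of 1 wildtype sum would appear as a batch difference, and the p-values do not cover it. Khdc3, a subcortical complex member, had a mutant fold of 2.64 in batch 1 and -0.78 in batch 2, and Srm, spermidine synthase, 2.48 and -1.03, both with an edgeR adjusted p of 0.00482. Nlrp2 went the other way, at -2.40 and 0.21 with the same adjusted p from edgeR. In all, 45 of 13566 genes differed (9 higher and 36 lower in batch 2), 4 of them among the 1298 above, and 1381 had an unadjusted p under 0.05. With a mutant sum left out the count ran from 16 (M2, batch 1) to 372 (M1, batch 2). It was 169 by DESeq2, 11 by voom, 235 without the filter on low counts 119 without the 9 wildtype eggs whose counts lay in few genes, and 18 without egg 8 of M3. The 3 genes were chosen after their values were seen, and in batch 2 each plate held 1 genotype.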

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

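The alternatives of the test of batch difference were chosen only after its result was seen. Wildtype egg 1 of batch 1 had a total of 2609358 counts, and the next lowest of the 5 eggs had 7837230. Its gap of 0.801 of the group's range stood past the 95% critical value for 5 samples, in 14 combinations of group and measure tested, of which chance alone passes about 5%.

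The mutant effect differed between batches for 45 genes by edgeR's interaction test. With 1 wildtype sum per batch, a deviation of a single wildtype sum would also appear as such a difference. Tdrd5, of the germline Tudor family, had a mutant log2 fold of 1.61 in batch 1 and -1.28 in batch 2, Akr7a5, an aldo-keto reductase, 2.05 and -1.79, Tubb2b 2.84 and -0.09, and Drg1 2.70 and -1.12. The number of genes was 169 by DESeq2 and 11 by voom, 235 without the filter on low counts, and 119 without 9 wildtype eggs of batch 2 that had over 35% of counts in 50 genes. Without egg 8 of M3 it was 18. With 1 mutant sum left out it was 292 and 372 (M1, batch 1 and batch 2), 16 and 216 (M2), and 85 and 85 (M3).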

How the results depend on the processing

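Tests chosen only after the data were seen were those without near-empty eggs, egg 8 of M3, eggs 6 and 21 of M1 or the 9 wildtype eggs with over 35% of counts in 50 genes, those on the plates of the deposited table, the alternatives of the batch difference, and the correlation without the zygotic list or with a sum left out. No paired analysis was possible because replicate numbers only count eggs within a group and the tested sums carry no number, while the batch or plate that sums share was a term in the fits reported. Of 5325 values of named genes under other settings, 4787 kept direction and side of the threshold, 523 no longer passed, 5 newly passed and 10 reversed, and the cause was not tested. All reversals came with means of log2 CPM over eggs, with all eggs and without near-empty ones: Tubb6 (0.90 and 0.73) and Duxf3 (-0.25 and -0.70) in mutant against wildtype, and Pfn1 (0.23 and 0.25), Zp3 (0.082 and 0.12) and Hsph1 (0.42 and 0.46) in activated against wildtype. Those means called 3700 and 4564 genes for mutant against wildtype (3404 higher and 296 lower, then 2748 and 1816), 6277 and 5852 for activated against wildtype, 2885 and 3665 for mutant against activated (1462 higher and 2203 lower in the latter), 2 for M2 against M1 (all eggs) and 0 for M3 against M1 (without near-empty eggs). With the same means 1199 and 1236 of the 1298 genes called between mutant and wildtype, 1760 and 1761 of the 1797 between activated and wildtype, and 669 and 670 of the 670 between mutant and activated kept their direction. In these means a count of 0 scored higher in shallower eggs, so they can also carry differences in depth. For mutant against wildtype a fold of at least 2 left 814. No batch term left 51, 196 and 35 (3 higher and 32 lower) for the first 3 comparisons, and sums per plate left 409, 666 and 161. Without a filter there were 1099 for mutant against activated, 45 for M2 against M1, 130 for M3 against M1 and 44 for M3 against M2, and DESeq2 called 1038, 28, 59 and 2. Voom called 4 for M2 against M1 and 3 for M3 against M2, and eggs thinned to equal depth gave 13 for M3 against M1. The 6 genes of M3 against M1 were 0 without the plate block, 0 with the deposited plates and 0 without eggs 6 and 21 of M1. With 1 sum left out the counts ran from 755 to 1262 (mutant against wildtype), 1433 to 2106 (activated against wildtype), 380 to 1119 (mutant against activated, 380 and 423 without M1 or M2 of batch 2, 1078 and 1119 without wildtype of batch 1 or 2), 0 to 3 (M2 against M1), 0 to 11 (M3 against M1), 0 to 2 (M3 against M2) and 16 to 372 (batch difference). The batch difference was 169 by DESeq2, 11 by voom, 235 without a filter, 119 without the 9 wildtype eggs and 18 without egg 8 of M3. The calls of gene lists were 0 with an estimated correlation and 0 with fry in all 5 comparisons that had any. The correlation of responses was 0.519 from 4 log2 CPM, 0.648 with shared eggs and 0.234 to 0.300 with a sum left out. Thinning moved the median log2 fold of all genes from 0.06 to -0.05 for mutant against wildtype and from 0.15 to 0.01 for activated against wildtype, and upper quartile scaling moved it from -0.05 to -0.20 for mutant against activated. Depth was lowest in the batch 2 wildtype sum (5436993 counts), where 1 count is the smallest step, and limits low genes such as Cdc25c there.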

Other observations

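Tests of depth, of reads from activated eggs and of a swapped egg, the subset of zygotic members low in wildtype eggs, the gene set of the activation score in its present form, and the tolerance of 0.05 set on the correlation were chosen only after results had been seen. A first score used all called genes, batch 1 eggs included, and was replaced so that batch 1 eggs took no part.

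Egg 8 of M3, from plate 1 of batch 2 (490016 counts), held transcripts of zygotic activation at 9480 CPM, with Usp17le at 1005, Usp17lb at 760, Usp17la at 745, Eif1ad8 at 280, Zscan4d at 270 and Zfp352 at 170 counts. Wildtype eggs together held 0 counts of Zfp352 and Usp17la, and the other mutant eggs 13 and 65. Of these, 12 and 60 came from M3 egg 1 of batch 1 (6029146 counts). Its zygotic members low in wildtype stood at 39 CPM, the highest among mutant eggs apart from egg 8. In egg 8 Mos had 0 counts, 8373 genes were detected at 60000 counts, mitochondrial transcripts were 2.69% of counts, and blood markers stood at 322 CPM. In activated eggs the members low in wildtype had medians of 407 CPM with a growth number of 1 (8 eggs) and 645 with 2 (9 eggs), within ranges that overlapped.

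Genes that differed between mutant and wildtype eggs were weighed against 3 technical explanations. A plate effect was argued against by plate A of batch 1, which held 5 wildtype and 2 mutant eggs. Genes chosen by their batch 2 fold went the same way there in 88% of 910, 35.2 points above independent signs. The 2 mutant eggs were M3 egg 1 and M1 egg 6, the latter with Mos above each wildtype egg of its batch. The test was not repeated without M1 egg 6. Gene length and GC content left 91.9% of called genes with a length past the threshold once their trends were removed. At equal depth per egg 61.2% stayed past it, and all 1261 genes still tested kept their direction. What stays open, untested, is the Mos mutation itself and differences in maturation or culture between animals. Library complexity stays open as well, since thinning equalised depth only. At 60000 counts wildtype eggs of batch 2 held a mean of 5202 genes, against 6361 in mutant eggs. The 15 wildtype eggs without concentrated counts held 5574. Without the 9 others 1094 genes were called.

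The zygotic transcripts of egg 8 of M3 may have a technical source. Reads carried over from the activated eggs were argued against, since the egg held 3.14 times the list's CPM of the highest activated egg. A swap with an activated egg was argued against too. The egg's activation score, from genes outside the list, was -2.09, within the other mutant eggs (-3.32 to -1.08) and 1.98 SD below the lowest of 17 activated eggs (-1.27 to -0.0471, each scored on genes chosen without it). Its members low in wildtype stood at 8930 CPM, against at most 2410 in an activated egg. A sample from outside the 107 eggs stays open and was not tested, and no biological explanation was tested.

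The mutant and strontium responses correlated across genes, for which shared wildtype eggs could be the reason. Without a shared egg the correlation was 0.277, where a value under 0.1 had been set as the mark of that explanation, and the lowest with a sum left out was 0.234. Zygotic transcripts as the reason stay open: without their list the correlation was 0.277, but the list is 27 of 13832 genes, too few for that to decide. The plates and depths behind the folds may also contribute and were not tested here.

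A further hypothesis was that cytoplasmic polyadenylation elements, which control translation and stability of stored mRNA, mark genes that changed in mutants. In the last 100 bases of the 3' UTR, 14.9% of 671 higher and 23.3% of 507 lower genes had such an element, a difference of -8.37 points, against -6.92 to 2.61 in 10000 random matched draws (percentile 0.54). The difference lay outside the central 95% of draws, the range set beforehand for no relation. The bound set beforehand for a relation, more than 99% of draws, was met on 1 side but not as a central interval. Whether that bound was met is left undecided.

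For the mutant groups, other splits of the same 6 sums were counted. As many genes as in the real split were found in 10 of 10 splits for M2 against M1 (real 0, highest other 2), 1 of 10 for M3 against M1 (real 6, highest other 0) and 10 of 10 for M3 against M2 (real 0, highest other 0). With 10 splits a share under 0.05 cannot be reached. The 10 splits include ones in which a plate lies wholly on 1 side, whereas the real comparison has both groups on each plate.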
